A study of Mus musculus with 9 samples.

How the data were processed

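Lacrimal glands were collected from mouse embryos at E14.5 that had been flash frozen in embedding medium, and cDNA was amplified with the SMART-seq v4 kit and made into Nextera XT libraries, per the labels' protocols. The bcl2fastq 1.8.4, TopHat, Cufflinks and DESeq tools and the mm9 genome build are named in the submitters' processing notes, without a role or an order. The authors deposited whole-number counts per gene symbol for each library, which were used as deposited. The counter, its annotation and its strand setting are not given in the sources used here. Genes that overlap on opposite strands, such as Kcnq1ot1, and close paralogs, such as globins, stefins and Serpinb genes, are therefore uncertain. The authors' deposited tables of PI3K-aa and PI3K-aR against WT hold log2 fold changes, and the same deposited tables hold p-values and adjusted p-values. They come from the same libraries and are no independent evidence.

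The files held 23420 gene symbols, of which 21777 (93.0%) matched a gene name in a mouse annotation of a later build, so names alone were used and no coordinates are given. A table of all 9 libraries equalled the single files in 9 of 9 columns but had 27 symbols turned into dates, and the single files were used. Libraries were grouped by the genotype in their labels. Totals lay between 14644912 and 21481933 counts, and 16532 genes had at least 1 count. No pair of libraries was as close as sampling noise allows: the lowest chi-square per degree of freedom was 80.5. Replicates had r of 0.813 to 0.874 in WT, 0.739 to 0.760 in PI3K-aa and 0.660 to 0.689 in PI3K-aR on log2 CPM, across genes, which are not independent replicates. Between groups, r was 0.650 to 0.698 for WT with PI3K-aa and 0.610 to 0.647 for WT with PI3K-aR. For PI3K-aa with PI3K-aR it was 0.636 to 0.709, so PI3K-aR libraries were no closer to each other than to those of PI3K-aa. The median coefficient of variation of genes at 10 to 30 CPM was 52.1% in WT, 68.8% in PI3K-aa and 92.5% in PI3K-aR, against 5.23, 5.51 and 5.96% from counting alone. For genes above 1000 CPM it was 16.9, 5.81 and 10.6%.

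Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with TMM scaling and edgeR's expression filter (minimum count 10, minimum total 15). The filter left 12634 genes in 1 fit over all 9 libraries with group as the only term and 6 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" refer to this. Comparisons were PI3K-aa with WT, PI3K-aR with WT, PI3K-aR with PI3K-aa, and the mean of both mutant groups with WT. Where all libraries of a group were at 0, a fold is given as a lower bound against a floor of 3 counts over the group (0.0501 CPM in WT, 0.0558 in PI3K-aa, 0.0654 in PI3K-aR). Floors cover counting error only. Bootstrap intervals of medians resample the genes with their fold changes held fixed, so they do not measure the spread between libraries. Of all tested genes, 28.7, 26.6 and 15.9% had no overlap between the compared groups' CPM values in PI3K-aa vs WT, PI3K-aR vs WT and PI3K-aR vs PI3K-aa, which chance gives for 10% of genes with 3 libraries against 3.

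The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Named in each comparison were Pik3ca, Pik3cb, Egfr, Etv4, Etv5, Sox9 and Sox10. The rule added the 10 genes that rose and the 10 that fell with the largest fitted fold change among those past the threshold with no overlap and an average log2 CPM of at least 1, leaving out predicted and sex-linked genes. From each list described, 2 to 4 members were named, those past the threshold first; further members are named where they complete a count. The 29 lists covered PI3K pathway components, FoxO targets, FGF and ERK targets, FGF ligands with their receptors and heparan sulfate genes, the EGF family, IGF and insulin components, lacrimal bud regulators, Notch, Wnt, Hedgehog and BMP genes. They further covered sterol and lipid synthesis, glycolysis and hypoxia, ATF4 and amino acid genes, ribosome biogenesis, the cell cycle, p53 targets, and immediate early and heat shock genes. Cell type lists held markers of epithelium, surface keratinising epithelium, lens, periocular mesenchyme, skeletal muscle, cartilage and bone, endothelium, red blood cells, macrophages, neurons and Schwann cells, melanocytes and pigment epithelium, and retina. Each list was tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), again with the correlation estimated, and with fry. Members were also adjusted over the list alone.

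The method was tested on simulated counts drawn from the real means and library sizes for 12435 genes. With 50 genes changed per fold, the PI3K-aa comparison recovered 1, 6, 16 and 23 genes at 2-, 4-, 8- and 16-fold with 4 false calls, and the PI3K-aR comparison 0, 7, 15 and 24 with 2. For both mutants it recovered 1, 13, 17 and 27 with 4 false calls, and for PI3K-aR against PI3K-aa, with nothing changed, 0 genes were called. Of 5 lists of 20 genes shifted 2-fold, 5 were recovered in each comparison with WT, and 0 of 24 unshifted lists were called. These genes were drawn independently, so the simulation does not test lists whose members are correlated. In the data the estimated correlation reached 0.692 for the skeletal muscle list in PI3K-aR vs WT. For single genes, changes of 2- to 8-fold were therefore mostly missed at this spread, and many 16-fold changes were missed too. A gene that did not pass may still have changed by a large fold. The overlap of the mutant comparisons was set beside 20 simulations of unchanged groups.

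The alternatives were DESeq2 size factors, no filter on low counts, the replicate number as a block, a fit of the compared groups alone, leaving out each library in turn, the Wald test of DESeq2 1.42.0 over all libraries, limma voom with sample weights, estimated correlation, fry, and a threshold of 0.1 on the authors' deposited tables. No value columns were left unmapped. Xist and Y-linked genes were kept out of the named genes.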

Results

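RNA sequencing was carried out on lacrimal glands of mouse embryos at E14.5, when this tear gland is an epithelial bud growing into the mesenchyme around the eye. The 9 libraries fell into 3 groups of 3. WT libraries carried Le-Cre alone, a Cre driver active in the surface ectoderm of the eye, from which the gland epithelium derives. PI3K-aa libraries carried Le-Cre with floxed alleles of both PI3K alpha (Pik3ca) and PI3K beta (Pik3cb), the catalytic subunits of class I phosphoinositide 3-kinase. PI3K-aR libraries carried Le-Cre with floxed Pik3cb and, at Pik3ca, a floxed allele over an allele labelled RBD, the name of the subunit's Ras-binding domain. Total counts were 16847225, 20883732 and 19828722 in WT, 17749236, 21481933 and 15218196 in PI3K-aa, and 16278078, 14644912 and 16140960 in PI3K-aR. Between 12428 and 14355 genes had at least 1 count in a library, and 12634 genes were tested. Levels are given as CPM, counts scaled by each library's normalised total, as mean ± SD (n = 3 libraries per group). Fold changes are log2 values of edgeR's quasi-likelihood fit, given ± SE. This SE was derived as the absolute log2 fold change divided by the square root of the test's F statistic, so it restates the test. The labels do not say that the 3 libraries of a group came from separate embryos, so p-values measure only the spread between these libraries, which may be technical.

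The transcripts of the targeted genes were looked at first. Pik3ca stood at 12.8 to 35.9 CPM in the WT libraries, at 68.2 to 94.6 CPM in PI3K-aa and at 35.6 to 68.7 CPM in PI3K-aR. Its fold changes against WT were 1.88 ± 0.65 in PI3K-aa (edgeR adjusted p = 0.149) and 1.10 ± 0.64 in PI3K-aR (edgeR adjusted p = 0.377), and neither passed the threshold. Pik3cb stood at 20.6 ± 13.1 CPM in WT, 20.3 ± 25.3 CPM in PI3K-aa and 3.47 ± 2.74 CPM in PI3K-aR, and did not pass the threshold either (edgeR adjusted p = 0.998 and 0.358). The files count reads per gene and not per exon, so a transcript that lacks floxed exons is still counted, as is RNA of cells without Cre. These levels therefore do not check the genotype labels.

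**Figure D1:**
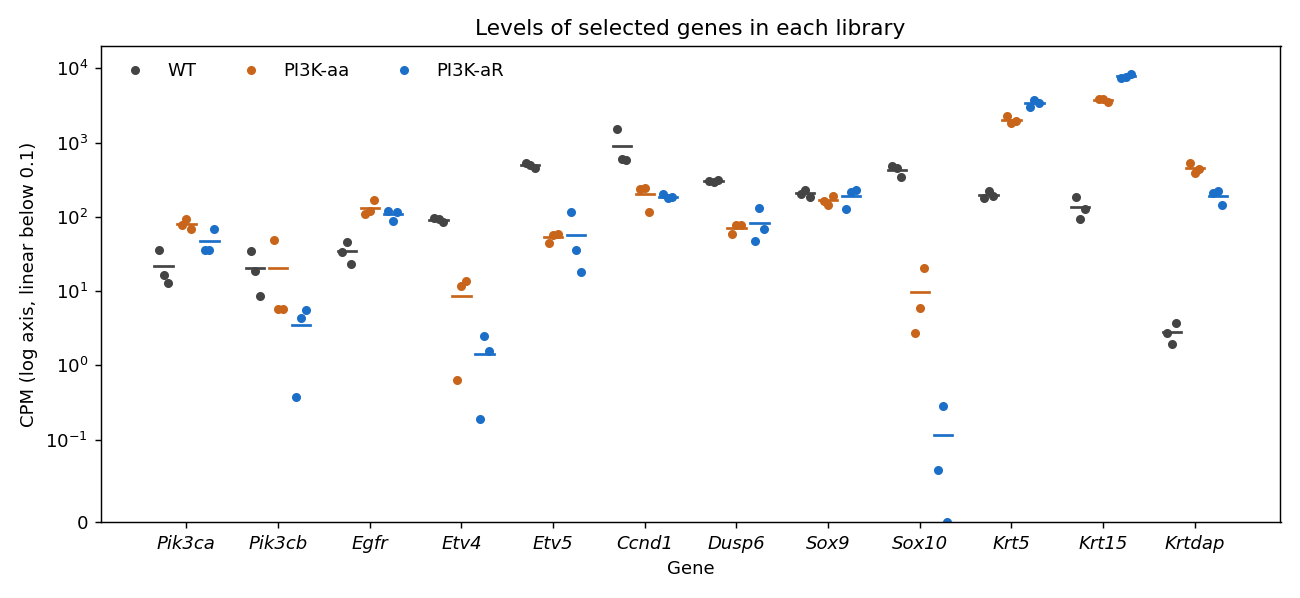
CPM of 12 genes in each of the 9 libraries, on a log axis that is linear below 0.1; points are libraries, in WT, PI3K-aa and PI3K-aR order, and bars are group means. Etv5, Ccnd1, Dusp6 and Sox10 lie lower in all 6 mutant libraries than in the 3 WT libraries, and Krt5, Krt15 and Krtdap lie higher.

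The comparison of PI3K-aa with WT asked how libraries labelled with floxed alleles of both catalytic subunits differed from those with Le-Cre alone. Sox10, a transcription factor of the gland bud, fell from 432 ± 73.8 to 9.75 ± 9.43 CPM (-5.47 ± 0.71, edgeR adjusted p = 0.000167). Etv5, a transcription factor switched on by FGF signalling, fell from 495 ± 44.3 to 53.1 ± 7.50 CPM (-3.22 ± 0.52, edgeR adjusted p = 0.00155). Krt15, a keratin of basal epithelium, rose from 136 ± 47.0 to 3748 ± 176 CPM, and Krtdap, a keratinocyte differentiation protein, from 2.80 ± 0.893 to 453 ± 68.4 CPM. In all, 303 genes rose and 154 fell, and 2017 genes had an unadjusted p under 0.05. These and the list changes below stand beside a periocular mesenchyme sum of 7958 ± 63.9 CPM against 1193 ± 311 CPM in WT and a surface keratinising sum of 1710.1 ± 107 CPM against 257 ± 38.2 CPM. They also stand beside higher shares of the RNAs Rn45s (2.07 to 2.20% of counts against 0.467 to 0.891%) and Malat1 (0.637 to 0.670% against 0.0629 to 0.0746%).

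Of the 19 FGF and ERK target genes, 0 rose and 5 fell (6 adjusted over the list alone), and the list was lower than other genes (camera adjusted p = 5.48e-06). Beside Etv5, cyclin D1 (Ccnd1) fell from 901 ± 544 to 200.3 ± 72.4 CPM and the ERK phosphatase Dusp6 from 307 ± 9.83 to 71.1 ± 11.2 CPM. Etv4, a close relative of Etv5, stood at 91.4 ± 6.04 CPM in WT and 8.65 ± 7.00 CPM in PI3K-aa without passing the threshold (edgeR adjusted p = 0.124, and 0.00807 to 0.327 over the alternatives). It passed with DESeq2, with limma voom, without the filter and in a fit of the compared groups alone. Of the 16 lacrimal bud regulators, 2 fell (Sox10 and Etv5) and 1 rose, the eye-field factor Pax6, with 5 and 4 adjusted over the list alone. The list was lower, with camera adjusted p = 0.0236 and adjusted p = 0.0792 with an estimated correlation. Sox9, another bud regulator, did not pass the threshold, at 207 ± 24.1 CPM in WT and 167 ± 23.3 CPM in PI3K-aa (edgeR adjusted p = 0.739). The receptor gene Egfr rose from 34.3 ± 11.6 to 133 ± 32.6 CPM (1.95 ± 0.45, edgeR adjusted p = 0.0194). This call was lost without WT replicate 3, PI3K-aa replicate 2 or PI3K-aa replicate 3, with adjusted p from 8.41e-06 to 0.125 over the alternatives.

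Metabolic and growth lists were lower as well. Of 26 glycolysis and hypoxia genes, 0 rose and 9 fell (1 and 11 adjusted over the list alone; camera adjusted p = 8.79e-12). Among them were Ldha, from 3121 ± 277 to 732 ± 35.0 CPM, Pkm, from 2352 ± 258 to 570.5 ± 49.5 CPM, and Aldoa, from 1649 ± 89.4 to 449 ± 92.6 CPM. Of 30 cell cycle genes, 3 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 1.93e-09). Rrm2, a subunit of ribonucleotide reductase, fell by 3.13 ± 0.47 on the log2 scale, and the mitotic kinase gene Cdk1 fell by 1.76 ± 0.31. Of 17 ATF4 and amino acid genes, 2 fell (2 adjusted over the list alone), the serine synthesis gene Psat1 and the amino acid transporter Slc7a5, and the list was lower (camera adjusted p = 0.000188). Of 22 ribosome biogenesis genes, 2 fell, Npm1 and Dkc1 (6 adjusted over the list alone; camera adjusted p = 1.50e-05). None of 28 sterol and lipid synthesis genes passed the edgeR threshold (0 adjusted over the list alone; 6 at an unadjusted p under 0.05, and 2 each by DESeq2 and by limma voom), and their median of -0.86 was lower than that of other genes (camera adjusted p = 0.000234). These 5 lists and the FGF and ERK targets remained lower with an estimated correlation.

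Epithelial lists moved upward. Of 14 genes of surface keratinising epithelium, 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 2.33e-15). Beside Krtdap these included Krt6a, from 19.7 ± 6.66 to 220.3 ± 19.7 CPM, and Sfn, from 178 ± 55.2 to 629 ± 122 CPM. Of 36 general epithelium genes, 8 rose and 2 fell (9 and 4 adjusted over the list alone). Krt5, a basal keratin, rose from 199.7 ± 22.1 to 2036 ± 227 CPM, whereas Epcam, an adhesion molecule of simple epithelia, fell from 1686 ± 209 to 498 ± 27.2 CPM. This list was higher by camera (adjusted p = 0.000198), and had adjusted p = 0.0567 with an estimated correlation.

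Markers of the mesenchyme around the gland were also higher. Of 23 periocular mesenchyme genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 2.03e-23). Dcn, a matrix proteoglycan, rose from 47.4 ± 13.3 to 1086 ± 84.2 CPM and Col1a2 from 141 ± 66.7 to 1744 ± 106 CPM. Dct, a pigment cell enzyme, rose from 0.439 ± 0.177 to 124 ± 35.9 CPM. It was the 1 of 6 melanocyte and pigment epithelium genes that rose, and Rlbp1, a retinoid-binding protein, fell (3 and 1 adjusted over the list alone). That list had camera adjusted p = 0.0366 and adjusted p = 0.362 with an estimated correlation. Skeletal muscle genes did not pass the edgeR threshold (0 of 20; 2 rose adjusted over the list alone; 5 had an unadjusted p under 0.05, 1 passed by DESeq2 and 0 by limma voom; camera adjusted p = 0.507).

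Of 16 IGF and insulin components, Igf2, Igf1 and Igfbp2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 2.37e-05, adjusted p = 0.0792 with an estimated correlation). The growth factor gene Igf2 went from 253 ± 18.2 to 4755 ± 214 CPM. Among 14 Hedgehog and BMP target genes, the BMP response genes Id1 and Id3 rose, Id3 from 45.1 ± 4.40 to 1043 ± 73.9 CPM, while the related Id2 and Id4 fell. The list was higher (3 up and 2 down adjusted over the list alone; camera adjusted p = 2.37e-05, adjusted p = 0.0503 with an estimated correlation). Among 16 Wnt target genes, Lef1, Wif1 and Lgr5 rose and Sfrp1, which encodes a secreted Wnt inhibitor, fell from 1132 ± 139 to 274 ± 26.0 CPM. The list was higher (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0146, adjusted p = 0.0739 with an estimated correlation). Of 18 p53 target genes, the cell cycle inhibitor Cdkn1a and the death receptor Fas rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0375, adjusted p = 0.0896 with an estimated correlation). In the cartilage and bone list, the moved members were the fibrillar collagen gene Col2a1 and the collagen IX genes Col9a1 and Col9a3, which fell, Col9a1 from 611 ± 52.5 to 26.7 ± 16.3 CPM, and Hapln1, a matrix link protein, which rose. The list was lower (3 up and 3 down adjusted over the list alone; camera adjusted p = 0.0236, adjusted p = 0.0809 with an estimated correlation).

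Among the 20 genes named by size of change, Sema3e, a guidance cue, had no count in WT and stood at 10.8 ± 15.4 CPM in PI3K-aa, at least 216-fold higher. Its counts there were 65, 5 and 433, so that PI3K-aa replicate 3 carried most of this bound, and the call was lost in 5 of the fits with a library left out. Serpinb10, Klhl14, Npy, Pgam2, Npy1r, Plxdc1, the ligand gene Wnt3, Dct and Serpinb11 rose from WT means under 1 CPM, Npy1r from 0.125 ± 0.0740 to 51.5 ± 12.3 CPM. Fam150b, a ligand of receptor tyrosine kinases, fell from 323 ± 53.9 to 1.95 ± 2.04 CPM, Wfdc18 from 878 ± 44.1 to 7.01 ± 6.54 CPM. Likewise the potassium channel gene Kcnn4 fell from 375 ± 118 to 2.41 ± 2.57 CPM, and the secreted protein gene Lcn2 from 153 ± 36.2 to 1.09 ± 0.949 CPM. Gpx2, Cited4, Hs3st3a1, a heparan sulfate sulfotransferase gene, Fbxo32, Fzd9 and Noxo1 fell too, each to a mean under 3 CPM. Of these 20, 7 passed with each library left out in turn (Npy1r, Dct, Fam150b, Kcnn4, Gpx2, Wfdc18 and Noxo1). The count of 457 genes dropped to 246 without WT replicate 3, 290 without WT replicate 2, and 291, 297 and 278 without PI3K-aa replicates 1, 2 and 3.

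The comparison of PI3K-aR with WT asked the same of libraries labelled with the RBD allele beside the floxed ones. Sox10 fell from 432 ± 73.8 to 0.116 ± 0.149 CPM (-11.84 ± 0.99, edgeR adjusted p = 1.64e-06), and Etv5 from 495 ± 44.3 to 56.6 ± 52.3 CPM (-3.13 ± 0.52, edgeR adjusted p = 0.00176). Etv4 fell from 91.4 ± 6.04 to 1.41 ± 1.15 CPM (-6.01 ± 1.27, edgeR adjusted p = 0.01004). Krt15 rose to 7796 ± 423 CPM and Krt5 to 3387 ± 383 CPM, from 136 ± 47.0 and 199.7 ± 22.1 CPM in WT. Contractile genes of skeletal muscle appeared, with Acta1 at 584 ± 67.6 CPM against 0.303 ± 0.445 CPM in WT. In all, 380 genes rose and 271 fell, and 2483 genes had an unadjusted p under 0.05.

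Of the 20 skeletal muscle genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone), and their median fold change, with genes absent from WT at their bound, was 8.24. The camera call (adjusted p = 4.46e-27) was lost with an estimated correlation, at adjusted p = 0.0654 with an estimated correlation. The giant sarcomere gene Ttn had no count in WT and stood at 499.97 ± 123 CPM, at least 9982-fold higher. The myosin light chain gene Myl1 stood at 454 ± 54.7 CPM, at least 9071-fold higher. The summed level of the list was 4029, 4032 and 4096 CPM in the 3 PI3K-aR libraries, against 19.7 ± 2.58 CPM in WT and 23.0 ± 32.6 CPM in PI3K-aa. All other differences between PI3K-aR and WT stand beside this muscle level and beside higher shares of Rn45s (2.54 to 2.75% of counts against 0.467 to 0.891% in WT) and Malat1 (0.653 to 0.761% against 0.0629 to 0.0746%).

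Of the 19 FGF and ERK target genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 1.22e-06). Ccnd1 fell to 188 ± 13.0 CPM and Dusp6 to 82.2 ± 44.0 CPM. Of 26 glycolysis and hypoxia genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 5.47e-07). Ldha fell to 971 ± 81.3 CPM and Gapdh from 2634 ± 509.9 to 849.9 ± 137 CPM. Of 30 cell cycle genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 1.01e-07). Cdk1 fell from 431 ± 49.5 to 94.6 ± 29.8 CPM, and Tyms, a thymidylate synthesis gene, from 394 ± 86.5 to 104 ± 41.7 CPM. These 3 lists remained lower with an estimated correlation. Of 17 ATF4 and amino acid genes, Slc7a5, Psph and Slc3a2 fell (5 adjusted over the list alone; camera adjusted p = 0.000154, adjusted p = 0.0632 with an estimated correlation). Of 22 ribosome biogenesis genes, Ncl and Npm1 fell (4 adjusted over the list alone; camera adjusted p = 0.00231, adjusted p = 0.0677 with an estimated correlation). Of 16 bud regulators, Sox10, Etv5 and Etv4 fell, and Pax6 and Barx2, an epithelial homeobox gene, rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.0895 with an estimated correlation).

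Of 14 surface keratinising genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.91e-14). Calml3, a calmodulin-like protein of keratinocytes, rose from 6.72 ± 6.59 to 295 ± 57.6 CPM and Krtdap to 192 ± 40.8 CPM. Of 36 epithelium genes, 7 rose and 1 fell, Epcam (10 and 4 adjusted over the list alone; camera adjusted p = 1.52e-05). Of 23 periocular mesenchyme genes, 8 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 3.12e-10). Dcn rose to 365 ± 51.2 CPM and Col1a2 to 605 ± 68.0 CPM, and the summed level of the list was 3717 ± 498 CPM. These 3 lists remained higher with an estimated correlation. Igf2, Igf1 and Igfbp5 rose among 16 IGF and insulin components (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.000154, adjusted p = 0.107 with an estimated correlation). Id1 and Id3 rose and Id2 and Id4 fell among 14 Hedgehog and BMP targets (4 and 2 adjusted over the list alone; camera adjusted p = 0.000154, adjusted p = 0.0677 with an estimated correlation). Wif1, Lef1 and Lgr6 rose and Sfrp1 fell among 16 Wnt targets (5 and 1 adjusted over the list alone; camera adjusted p = 0.0252, adjusted p = 0.0881 with an estimated correlation). In the cartilage and bone list, Col9a1, Col9a3 and Col2a1 fell and Hapln1 rose (3 up and 4 down adjusted over the list alone). The test and the mean (-0.52) were downward and the median (1.14) upward, with camera adjusted p = 0.0258 and adjusted p = 0.0895 with an estimated correlation.

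Among the 20 genes named by size, the 10 that rose had no count in WT. They were Ttn, Myl1, Tnnc1, Neb, Myh8, Csrp3, Tceal7, Tnni2, Cav3 and Cpne7, with Cpne7 at 34.4 ± 4.97 CPM and at least 687-fold higher. Wfdc18, Fam150b, Gpx2, Plek2, Bace2, Cdk18, Cldn9 and Ydjc had no count in PI3K-aR, Wfdc18 being at least 13426-fold lower and Fam150b at least 4944-fold lower than in WT. Kcnn4 fell from 375 ± 118 to 0.0211 ± 0.0366 CPM. With Sox10 these made up the 10 that fell. Egfr rose to 108 ± 17.3 CPM (1.65 ± 0.44, edgeR adjusted p = 0.0400), and Sox9 did not pass the threshold, at 191 ± 56.3 CPM (edgeR adjusted p = 0.895). The Egfr call was lost in 8 of the 9 fits that left out a library, with a replicate block and in a fit of the compared groups alone, with adjusted p from 0.000102 to 0.186 over the alternatives. Among the 20 genes named by size, Cav3, Cpne7, Cdk18 and Cldn9 lost theirs in at least 1 such fit. The count of 651 genes dropped to 330 without WT replicate 3 and 391 without WT replicate 2.

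**Figure D2:**
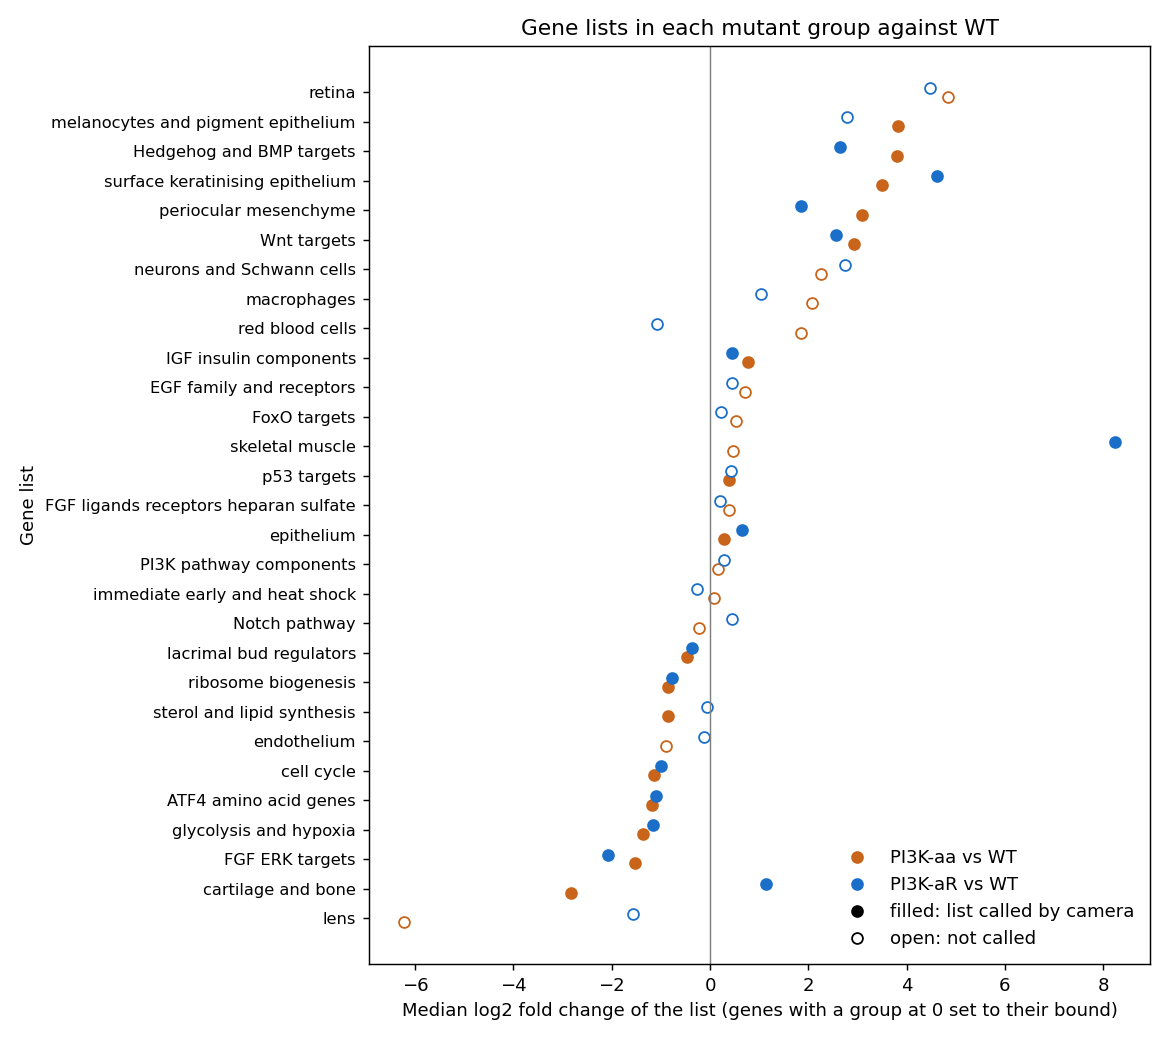
Median log2 fold change against WT (horizontal axis) of the 29 gene lists (vertical axis) in PI3K-aa and PI3K-aR, with genes absent from 1 group set to their bound; filled points are lists called by camera at an adjusted p under 0.05. The skeletal muscle median is 8.24 in PI3K-aR and 0.46 in PI3K-aa, and the FGF and ERK targets lie at -2.08 and -1.52.

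Lists without a camera call against WT held few called genes in number, as did some of the lists that were called. Of 21 PI3K pathway components, 0 passed the edgeR threshold in either comparison (1 fell in PI3K-aa adjusted over the list alone and 0 in PI3K-aR). By an unadjusted p under 0.05, by DESeq2 and by limma voom, 3 passed in PI3K-aa and 1 in PI3K-aR (camera adjusted p = 0.740 and 0.618). Akt1, a kinase activated by PI3K, stood at 399 ± 101 CPM in WT, 145 ± 66.6 CPM in PI3K-aa and 246 ± 116 CPM in PI3K-aR. Of 22 FoxO target genes, Txnip and Cited2 rose and Fbxo32 fell in both comparisons, and Ccnd2 rose in PI3K-aa (3 up and 2 down in PI3K-aa and 3 up and 1 down in PI3K-aR adjusted over the list alone; camera adjusted p = 0.407 and 0.507). With a library left out, the Cited2 and Fbxo32 calls were lost in 4 and 3 of 9 fits in PI3K-aa and in 7 and 8 of 9 in PI3K-aR, where Fbxo32 had 4, 364 and 4 counts. Of 14 EGF family genes, Egfr rose in both, and Lrig3 rose in PI3K-aR (3 up and 1 down in each adjusted over the list alone; camera adjusted p = 0.257 and 0.588). Of 20 genes for FGF ligands, FGF receptors and heparan sulfate, Sdc1 rose in both, and in PI3K-aR Fgf9 rose and Fgf1 fell (2 up and 1 down, and 4 up and 1 down, adjusted over the list alone; camera adjusted p = 0.443 and 0.588). Of 20 immediate early and heat shock genes, the heat shock genes Hspb1 and Hspa1a rose in both, Hspb1 from 44.9 ± 12.7 to 455 ± 61.0 CPM in PI3K-aa. In this list Nr4a1, an immediate early gene, fell in PI3K-aa and Hspa1b rose in PI3K-aR (2 up and 2 down, and 3 up and 0 down, adjusted over the list alone; camera adjusted p = 0.390 and 0.568). None of 15 Notch pathway, 11 macrophage and 10 endothelium genes passed by edgeR in either comparison (0 adjusted over the list alone; camera adjusted p = 0.462 and 0.618, 0.199 and 0.507, and 0.481 and 0.139). In PI3K-aa, 2 genes of each of these lists had an unadjusted p under 0.05, with 2, 2 and 1 passing by DESeq2 and 2, 3 and 1 by limma voom. In PI3K-aR, 4, 3 and 3 had an unadjusted p under 0.05, with 4, 1 and 2 passing by DESeq2 and 2, 1 and 0 by limma voom.

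Among 10 neuron and Schwann cell genes, Fabp7, a fatty acid binding protein, fell from 249.9 ± 14.3 to 4.54 ± 2.43 CPM in PI3K-aa and to 0.817 ± 0.358 CPM in PI3K-aR, and Ncam1 rose in PI3K-aR (3 up and 2 down, and 4 up and 1 down, adjusted over the list alone; camera adjusted p = 0.681 and 0.190). Lens genes had 1 rise each, Cryab in PI3K-aa and Bfsp1 in PI3K-aR (12 genes; 2 up and 1 down, and 1 up and 0 down, adjusted over the list alone; camera adjusted p = 0.417 and 0.618). The medians of the lens list were -6.22 in PI3K-aa and -1.57 in PI3K-aR, and its summed CPM in the WT libraries was 352, 66.3 and 147. The sum was 188 ± 147 CPM in WT, 224 ± 61.3 CPM in PI3K-aa and 174 ± 62.8 CPM in PI3K-aR, so it did not follow the medians. Bfsp1 had 3, 1035 and 54 counts in the PI3K-aR libraries, and its call was lost in 7 of the fits with a library left out, as that of Cryab was in 6. Of 8 retina genes Rlbp1 fell in PI3K-aa and 0 passed by edgeR in PI3K-aR, where 5 had an unadjusted p under 0.05 and 3 passed by DESeq2 and 0 by limma voom (4 up and 1 down in each adjusted over the list alone; camera adjusted p = 0.303 and 0.0813). Of 4 red blood cell genes, the embryonic globin gene Hbb-y rose from 4.85 ± 4.19 to 61.6 ± 13.1 CPM in PI3K-aa and to 376 ± 115 CPM in PI3K-aR, and Hba-x rose in PI3K-aR (2 up and 1 down, and 2 up and 2 down, adjusted over the list alone; camera adjusted p = 0.142 and 0.221). In the PI3K-aR comparison, Cdkn1a rose among p53 targets (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.535) and Scd1 fell among sterol and lipid synthesis genes (0 up and 1 down; 0.454). In PI3K-aR 0 of 6 melanocyte and pigment epithelium genes passed by edgeR (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.618), while 2 had an unadjusted p under 0.05 and 2 passed by DESeq2 and 0 by limma voom. In PI3K-aR, median and mean differed in sign for the EGF family, FGF ligand, Notch and p53 lists. Median and test differed there for the red blood cell and immediate early lists, and in PI3K-aa median and mean did for the FoxO list.

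The direct comparison of PI3K-aR with PI3K-aa asked whether the mutant genotypes differed from each other. Skeletal muscle genes were higher in PI3K-aR: 11 of 20 rose and 0 fell (19 and 0 adjusted over the list alone), with a median fold change of 8.11 and camera adjusted p = 5.96e-51. Mylpf rose from 3.59 ± 3.11 to 422 ± 39.1 CPM, Actc1 from 1.84 ± 3.07 to 558 ± 137 CPM, and Acta1 from 2.19 ± 3.24 to 584 ± 67.6 CPM. Periocular mesenchyme genes were lower, with 3 of 23 falling and 0 rising (5 and 0 adjusted over the list alone; median -1.04, camera adjusted p = 7.13e-06). Dcn fell by 1.57 ± 0.25, Col1a2 fell by 1.53 ± 0.27 and Lum fell by 1.99 ± 0.38 on the log2 scale. Sox10 fell further, from 9.75 ± 9.43 to 0.116 ± 0.149 CPM (-6.37 ± 0.87, edgeR adjusted p = 0.0112).

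In all, 23 genes rose and 30 fell in PI3K-aR relative to PI3K-aa, and 1387 had an unadjusted p under 0.05. The count was far higher with DESeq2, and with limma voom more genes rose than fell, as given below. All 10 genes named by size that rose were muscle genes (Myl1, Myh3, Neb, Myh8, Ttn, Actc1, Acta1, Tnnt2, Tnni1 and Tnnc1). Those that fell were Ydjc and Gpx2, which had no count in PI3K-aR and were at least 319.9-fold and 29.6-fold lower, and C1qtnf7, Pdxk, Adora2b, Sh3yl1, Nupr1, Adamts4, Scd1 and Pusl1. Nupr1, a stress response gene, fell from 14.7 ± 17.3 to 0.0631 ± 0.0634 CPM. Outside the muscle and mesenchyme lists, Krt15 rose by 1.06 ± 0.20, Igfbp5 by 1.64 ± 0.29, Psat1 by 2.01 ± 0.37 and Sfrp1 by 1.05 ± 0.21. The collagen gene Col9a1 fell from 26.7 ± 16.3 to 3.67 ± 2.60 CPM. Sterol and lipid synthesis genes had a median of 0.66 (camera adjusted p = 0.00477, adjusted p = 0.0749 with an estimated correlation), while the member that passed, the desaturase gene Scd1, fell (1 up and 1 down adjusted over the list alone). The muscle and mesenchyme calls remained with an estimated correlation, and the other 26 lists were not called. Median, mean and test differed in sign here for the PI3K component, FoxO, FGF ligand, bud regulator, Notch, Wnt target, Hedgehog and BMP, glycolysis, cell cycle, red blood cell and retina lists. Etv5 (0.09 ± 0.48), Etv4 (-2.61 ± 1.09), Egfr (-0.30 ± 0.43) and Sox9 (0.20 ± 0.31) did not pass in this comparison (edgeR adjusted p = 0.978, 0.389, 0.879 and 0.897), nor did Pik3ca (0.743) or Pik3cb (0.548). Of the 20 genes named by size, Myl1 alone passed with each library left out in turn, and the Sox10 call was lost with limma voom and in a fit of the compared groups alone (adjusted p from 4.64e-13 to 0.459 over the alternatives). The count of 53 genes dropped to 12, 7 and 25 without PI3K-aa replicates 1, 2 and 3 and to 20, 19 and 33 without PI3K-aR replicates 1, 2 and 3.

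**Figure D3:**
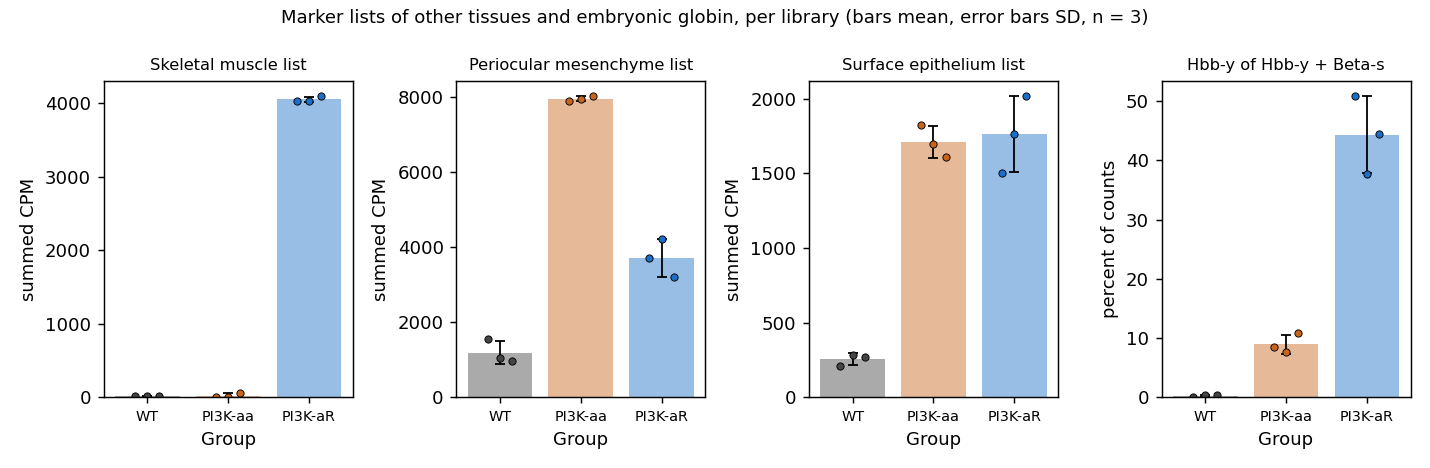
Summed CPM of the skeletal muscle, periocular mesenchyme and surface epithelium lists, and the percentage of Hbb-y in the counts of Hbb-y and Beta-s together, by group; bars are means, error bars SD and points the 3 libraries of a group. The muscle sum lies above 4000 CPM in the PI3K-aR libraries alone, the mesenchyme sum is 7958 CPM in PI3K-aa and 3717 CPM in PI3K-aR, and the Hbb-y share is 0.251, 9.01 and 44.3% in WT, PI3K-aa and PI3K-aR.

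The mean of both mutant groups was set against WT to ask how the mutants differed from WT on average, which 1 group alone can bring about. Wfdc18, Fam150b, Gpx2 and Kcnn4 fell from 878, 323, 262 and 375 CPM in WT to 7.01, 1.95, 1.94 and 2.41 CPM in PI3K-aa and to at most 0.0211 CPM in PI3K-aR. Falls were also seen for Sox10 (-8.66 ± 0.63, edgeR adjusted p = 2.42e-07), Etv4 (-4.71 ± 0.90, edgeR adjusted p = 0.00397) and Etv5 (-3.17 ± 0.40, edgeR adjusted p = 0.000113). Krt13, a keratin of stratified surface epithelium, Tmprss11g and the stefin gene Stfa3 rose, and so did Egfr (1.804 ± 0.41, edgeR adjusted p = 0.0128, lost without WT replicate 3; adjusted p from 6.22e-07 to 0.0978 over the alternatives). A total of 406 genes rose and 358 fell, and 2436 had an unadjusted p under 0.05. Pik3ca (1.49 ± 0.59), Pik3cb (-1.29 ± 1.13) and Sox9 (-0.21 ± 0.27) did not pass (edgeR adjusted p = 0.163, 0.603 and 0.751).

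The other genes named by size were Sema3e, Cwh43, Pgam2, Klhl14, Npy, Wnt3 and Gabrb1, which rose, and Odf3l1, Serpina9, Prss33, Slc26a9, Fam89a and Pglyrp1, which fell. Pglyrp1, a secreted antibacterial protein, stood at 17.4 ± 4.49 CPM in WT, at 0.149 ± 0.168 CPM in PI3K-aa and at 0 in PI3K-aR; Stfa3 stood at 0.0786 ± 0.0981, 10.4 ± 10.1 and 94.0 ± 18.6 CPM, and its reads may be shared with other stefin genes. Of 20 named genes, 12 passed with each library left out in turn. In both mutants against WT, 15 lists were called, 7 higher and 8 lower, and 10 remained with an estimated correlation. Bud regulators (2 of 16 rose and 4 fell, 3 and 4 adjusted over the list alone; camera adjusted p = 0.00442) and cartilage genes (1 of 9 rose and 3 fell, 3 and 4 adjusted over the list alone; camera adjusted p = 0.00231) were among these 10, at adjusted p = 0.0466 and 0.0448 with an estimated correlation, but both calls were lost with limma voom. The skeletal muscle list (7 of 20 rose, 15 adjusted over the list alone, though 0 of 20 passed in PI3K-aa; camera adjusted p = 2.40e-11) had adjusted p = 0.168 with an estimated correlation. The IGF (0.0807), Wnt target (0.0614), Hedgehog and BMP (0.0534) and sterol (0.0614) calls were lost with an estimated correlation too. In the same comparison 9 of 14 surface keratinising genes rose and 0 fell (10 and 1 adjusted over the list alone), and 11 of 23 mesenchyme genes rose and 0 fell (14 and 0 adjusted over the list alone), while Rn45s, a ribosomal precursor transcript, held 2.07 to 2.75% of counts in the mutants and 0.467 to 0.891% in WT. The count of 764 genes dropped to 413 without WT replicate 3 and 437 without WT replicate 2.

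The calls of the mutant groups overlapped. Of the 457 genes called in PI3K-aa and the 651 called in PI3K-aR, 244 rose in both and 101 fell in both, against 9.11 and 3.30 expected from independent lists. In 20 simulations, all 9 libraries were drawn from the WT means, with no change between groups. These gave 0, where 0 was expected as well for lack of calls, so that this value has no bearing on the overlap. The number called in opposite directions was 0 by edgeR (11 at an unadjusted p under 0.05), 10 by DESeq2 and 0 by limma voom. Across genes, which are not independent replicates, the fold changes of the mutant comparisons had r = 0.587 against 0.494 simulated, and a covariance of 3.00 against 0.846 simulated. The simulated comparisons shared their simulated WT libraries, so the simulated values already hold a part from shared controls at the fitted spread. The 3 WT libraries were too few to be split, so a larger part from the shared controls cannot be excluded. The overlap of 345 dropped to 184 without WT replicate 3, 222 without WT replicate 2 and 228 without PI3K-aa replicate 3.

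**Figure D4:**
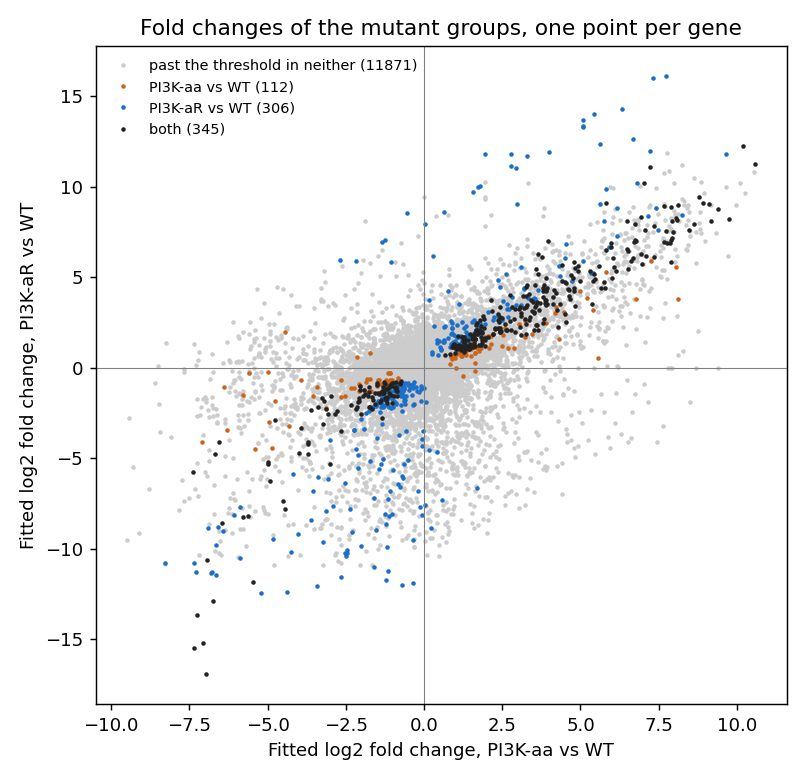
Fitted log2 fold changes of 12634 genes in PI3K-aa against WT (horizontal axis) and PI3K-aR against WT (vertical axis), coloured by the comparisons in which a gene passed the threshold; fitted values of genes absent from a group depend on the fit and are no measure of size. The 345 genes called in both comparisons lie in the upper right and lower left quadrants.

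The authors' deposited tables give their own comparisons of the same libraries. The authors' deposited table for PI3K-aa against WT held 2180 genes at an adjusted p under 0.05, 1206 higher and 974 lower. Of the 2079 genes of the authors' deposited table also tested here, 456 (21.9%) were called here, with r = 0.989 between fold changes across 12633 genes. The authors' deposited table for PI3K-aR against WT held 1907 genes, 1070 higher and 837 lower, and 635 of the 1838 tested here (34.5%) were called here, with r = 0.993 across 12630 genes. All 2079 and 1838 genes of the authors' deposited tables had the same direction here. Pik3ca had a log2 fold change of 1.88 and an adjusted p of 0.00335 in the authors' deposited table for PI3K-aa, where the edgeR fit gave 0.149. Etv4 had a log2 fold change of -3.40 and an adjusted p of 0.000413 in the same deposited table, where the edgeR fit gave 0.124.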

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

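Both tests of the muscle pattern were chosen after the result was seen, as was the count of other splits; the direct comparison of the mutant groups was planned. The results listed here differed between PI3K-aR and PI3K-aa, each set against the same WT libraries, in the direct test of that difference. By edgeR, 53 genes did. Of the 10 splits of these 6 libraries the real one alone, 1 of 10, gave as many (53 genes, highest other 0), and 10 splits cannot give a share under 0.05.

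Differences are PI3K-aR minus PI3K-aa in log2 units unless another unit is named. Contractile and other muscle genes were higher, namely Myl1 (8.66), Myh3 (8.61), Neb (8.59), Myh8 (8.59), Ttn (8.39), Actc1 (8.28), Acta1 (8.08), Tnnt2 (8.03), Tnni1 (7.98), Tnnc1 (7.97), Myl4 (7.88) and Mylpf (6.87). The median of the skeletal muscle list was 8.11. These folds rest largely on the few muscle reads of PI3K-aa replicate 3, as with Myl1, whose PI3K-aa counts were 0, 0 and 53. Higher as well were Psat1 (2.01), Igfbp5 (1.64), Krt15 (1.06) and Sfrp1 (1.05). The sterol and lipid synthesis list had a median of 0.66 (camera adjusted p = 0.00477, lost at adjusted p = 0.0749 with an estimated correlation), while its member Scd1 was lower (-7.43). The periocular mesenchyme list was lower (-1.04), and so were its members Lum (-1.99), Dcn (-1.57) and Col1a2 (-1.53). Col9a1 (-2.86) and Sox10 (-6.37) were lower too. Wfdc18, Gpx2 and Ydjc had no count in PI3K-aR, so their differences are bounds (at most -6.74, -4.89 and -8.32). Kcnn4 had 1 count in PI3K-aR, and its mean differed by -2.39 CPM.

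The muscle genes formed the clearest pattern. A single library as the source is argued against by the lowest summed muscle level of a PI3K-aR library, which was 66.6 times the highest of the other 6 libraries. Skeletal muscle cells in the PI3K-aR tissue pieces stay open. Of 12 muscle genes outside the lists 0 passed against WT, which met the bound first set against them. That bound was changed after the values were seen. The reason was their sum, 195 to 274 CPM in PI3K-aR libraries and 13.7 to 20.5 CPM in WT libraries. Their log2 fold changes ran from 1.61 to 7.26. Many 16-fold changes were missed in the simulation, so 0 passing cannot count against muscle cells. The sums of the 3 libraries, 4029, 4032 and 4096 CPM, are given as values, since the libraries may share a source. The labels do not say how the pieces were dissected, and an effect of the genotype was not tested and stays open.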

How the results depend on the processing

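The alternatives were planned, and the cause of a change was not tested unless named. The list calls kept their direction under every alternative run, but 8 of 48 were lost with limma voom: bud regulators and cartilage in each comparison with WT, and p53 targets and melanocyte genes in PI3K-aa vs WT. The melanocyte call was also lost with fry, without the filter and with the replicate block, and that of Wnt targets in PI3K-aR vs WT in the fit of the compared groups alone. Named genes, and list members past the threshold, kept theirs too, except Etv5 in PI3K-aR vs PI3K-aa, uncalled at 0.09 (-0.23 with the replicate block, -0.02 without PI3K-aa replicate 1, -0.99 without PI3K-aR replicate 1, -0.43 with limma voom). Further exceptions were uncalled Sox9 in PI3K-aR vs WT (0.11 without PI3K-aR replicate 1) and uncalled Pik3cb in PI3K-aa vs WT (0.58 without WT replicate 1, 0.42 and 0.43 without PI3K-aa replicates 2 and 3).

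Counts of genes in PI3K-aa vs WT, PI3K-aR vs WT, PI3K-aR vs PI3K-aa and both mutants vs WT were 1506, 2062, 876 and 1958 with DESeq2 and 1773, 912, 45 and 2089 with limma voom. Voom shifted the median of all genes to -0.18 in both mutants vs WT, and gave 30 higher and 15 lower in PI3K-aR vs PI3K-aa against 23 and 30. The overlap of the mutant comparisons was 919 with DESeq2 and 647 with voom. A fit of the compared groups alone gave 843 and 422 genes in PI3K-aa vs WT and PI3K-aR vs WT. Without the filter PI3K-aR vs PI3K-aa had 125 genes, with more genes tested. With an estimated correlation 8 lists were called in PI3K-aa vs WT and 6 in PI3K-aR vs WT. Pik3ca in PI3K-aa vs WT passed with DESeq2 (1.86) and voom (2.29), as it did in both mutants vs WT (1.51 and 1.91). Etv4 in PI3K-aa vs WT passed with DESeq2, voom, no filter and the compared groups alone (adjusted p from 0.00807 to 0.327 over all alternatives). Of the other named and list genes, the replicate block lost 55 calls, the fit of the compared groups alone 39, voom 18, DESeq2 size factors 5, DESeq2 3 and the fit without a filter 2.

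With each library left out, counts were 246 to 576 in PI3K-aa vs WT, 330 to 670 in PI3K-aR vs WT, 7 to 58 in PI3K-aR vs PI3K-aa and 413 to 863 in both mutants vs WT, with fewer samples in each fit. The overlap was 184 to 394. Lists called were 15 to 17, 14 to 15, 3 to 4 and 15 to 17. Called list members that passed in every such fit were 52 of 80, 65 of 104, 3 of 21 and 69 of 116. Ranges of fold changes were -1.83 to 0.58 for Pik3cb in PI3K-aa vs WT, -0.26 to 0.11 for Sox9 in PI3K-aR vs WT and -0.99 to 0.52 for Etv5 in PI3K-aR vs PI3K-aa.

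The replicate numbers did not pair the libraries: 9 same-number pairs had r of -0.019 to 0.029, none over 0.1, and 5 of 18 best matches were to the own number. The replicate block gave 399, 558, 27 and 667 genes and an overlap of 295. The spread between libraries at low counts was larger than counting alone gives, and its effect on which genes passed was not tested.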

Other observations

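The genes in this paragraph were chosen after their values were seen, and the fold changes are those of both mutants against WT in the edgeR fit. The Wnt ligand gene Wnt6 rose by 3.31 ± 0.25 (adjusted p = 3.44e-07), Wnt4 by 3.603 ± 0.38, Wnt10a by 3.71 ± 0.68 and Wnt7b by 7.34 ± 0.80. The uroplakin genes Upk1b and Upk3bl rose by 6.87 ± 0.67 and 4.31 ± 0.39. Gpha2, a glycoprotein hormone subunit gene, rose by 6.32 ± 0.57. Tfcp2l1, a transcription factor gene of duct epithelia, had a fold change of -7.89 ± 1.49. The imprinted genes H19 and Mest rose by 4.08 ± 0.17 and 2.25 ± 0.25, and the nuclear RNA Malat1 rose by 3.36 ± 0.15. Kcnq1ot1, an antisense transcript whose reads are uncertain without strand, rose by 4.21 ± 0.33, and the ribosomal precursor Rn45s by 1.94 ± 0.20. Malat1 held 0.0629 to 0.0746% of counts in the WT libraries, 0.637 to 0.670% in PI3K-aa and 0.653 to 0.761% in PI3K-aR.

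In the remaining part, the tests of the fetal growth genes were written before their values were seen, as 1 test that was later split by comparison; all other tests were chosen after the result was seen. Of the 10 splits of the 6 libraries in PI3K-aa vs WT and in PI3K-aR vs WT, 1 gave as many calls, the real one (457 and 651 genes, highest other 0 in each by edgeR), and 10 splits cannot give a share under 0.05. For both mutants against WT, 1 of 84 splits gave as many calls in a fit of 2 groups, the real one. It gave 623 genes against at most 30 in any other. The splits treat the libraries as separate units, which the labels do not state. If the libraries of a group share a source, this count cannot exclude chance.

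In both mutants against WT, Sox10, Etv4, Etv5 and Six1 fell among 16 bud regulators, of which Pax6 and Barx2 rose, and 9 of 14 surface keratinising genes rose and 0 fell. The median of the epithelium list was 0.328 (95% bootstrap interval 0.145 to 0.978), against -1.08 (interval -1.67 to -0.561) for all 33 tested bud and FGF target genes. This cannot decide on a lower share of epithelium as a whole, since those 33 genes include the falling Sox10, Etv4, Etv5 and Six1. The 36 epithelium genes also moved unevenly, 9 rising, with basal keratins such as Krt5 higher, and 3 falling. Schwann cells in the WT pieces as the source of Sox10 and Fabp7 are argued against by 6 Schwann cell markers, none above 2.01 CPM in a WT library, although Erbb3, a receptor of these cells that epithelia make too, had 17.97 to 41.0 CPM in WT, 0.284 to 2.76 in PI3K-aa and 8.72 to 24.6 in PI3K-aR. More surface epithelium in the mutant pieces stays open, and with it a lower share of gland epithelium (Epcam fell, -1.42): of 15 surface epithelium genes outside the lists, 7 rose and 0 fell, too few for the bound set for support, though they summed to 855 to 1484 CPM in the mutant libraries against 39.3 to 171 CPM in WT. A change of the gland epithelium through the genotype was not tested apart from this and stays open.

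The embryonic globin gene Hbb-y held 0.251 ± 0.213% of the Hbb-y and Beta-s counts in WT, 9.01 ± 1.61% in PI3K-aa and 44.3 ± 6.53% in PI3K-aR (n = 3; two-sided exact permutation p = 0.1 for each pair of groups, the smallest possible, 0.1 after adjustment over 3 comparisons). A different amount of blood alone as the source of this share is argued against by Beta-s, which fell (-1.93) while Hbb-y rose by 4.96. Globin RNA did differ in amount: Hbb-y, Beta-s and Hba-x summed to 2048 ± 236 CPM in WT, 717 ± 55.9 in PI3K-aa and 916 ± 187 in PI3K-aR. Misassigned paralog reads are argued against by the lowest mutant share, 18.8 times the highest WT share. Younger mutant embryos may explain the share against WT, and the median of 7 fetal growth genes, 0.594 (interval -0.160 to 1.07), leaves this open. Between the mutants that median was -0.185 (interval -0.760 to -0.0283), below 0, the bound set beforehand as counting against younger PI3K-aR embryos. That interval resamples the 7 genes and does not measure the spread between libraries. The mesenchyme list, whose cells may express these genes, was lower there too (-1.04), so the test carries little weight. An effect of the genotype was not tested and stays open.

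A hypothesis is that the mutant libraries were each made from pooled embryos of both sexes. All 6 mutant libraries held at least 100 reads of Xist, a transcript of female cells, and at least 100 of 4 Y-linked genes together, which is consistent with it. The WT libraries held 181, 418 and 537 Xist reads and 56, 7 and 11 Y-linked reads. Y-linked reads were 1514, 3162 and 1028 in the PI3K-aa libraries and 999, 521 and 620 in the PI3K-aR libraries. Xist reads were 289, 543 and 872 in PI3K-aa and 2201, 1466 and 1364 in PI3K-aR. Sex make-up thus differed along with genotype in every comparison with WT, and sex-linked reads differed between the mutant groups too. The effects of sex make-up and genotype cannot be told apart in any of these comparisons.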
